A study of Mus musculus with 6 samples.

How the data were processed

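Gene expression was measured on Affymetrix arrays in pancreatic islets of mice aged 5 weeks. Of the 6 arrays, 3 held RNA from wildtype mice and 3 held RNA from mice that lacked Sel1L in β cells only. The wildtype animals were littermates with floxed Sel1l alleles and no Cre recombinase, and the deficient animals carried a Cre gene inserted at a β-cell gene locus, per the labels' protocols. Islets were freed with an enzyme mixture, separated on a density gradient, picked by hand and left in culture overnight before RNA extraction. Total RNA was labelled with a whole-transcript sense-strand assay.

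The authors summarised the arrays with RMA, per the submitters' processing notes, a method that corrects background, normalizes between arrays and combines the probes of each probe set. The version, the filters and the log base were not given in the sources used here. The deposited values were treated as log2 values because all lay between 0.526 and 13.0 with array medians near 3, as RMA output on that scale does. RMA can pull large ratios toward 1, and bright probe sets approach the top of the scale. How far this compressed the fold differences was not measured here. The table carries no detection call, so a low value was not separated from background. No scan date or batch label was used here.

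The table held 41345 probe sets. Gene names came from the platform's annotation, which can be old. It gave 1 gene symbol for 23521 probe sets and several for 1814, and 16010 were unnamed here. Entrez identifiers of 23328 probe sets matched a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. Since the build behind the array design was not given, no coordinates are printed. Each gene was represented by its probe set with the highest mean over all 6 arrays, which gave 22180 genes, 1082 of them with more than 1 probe set. Every column of the table belonged to 1 of the 6 samples.

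Sel1L-deficient minus wildtype differences were tested per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all 22180 genes. An adjusted p under 0.05 was the threshold. Folds are 2 raised to the log2 difference. Errors are SD over 3 arrays for group values and the standard error from limma for differences. The replicates were described as islets from separately titled samples, and nothing in the labels says how many animals each array pooled, so p-values measure the spread between these samples.

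Before the data were examined, 27 gene lists with 476 members were fixed, of which 436 members were measured: ERAD machinery, ER chaperones and UPR, ATF4 and CHOP targets, mature β-cell identity, insulin granule and exocytosis, β-cell disallowed genes, progenitor and dedifferentiation, markers of α cells, of δ, PP and ε cells, and of acinar, duct, leukocyte, endothelial, mesenchymal and Schwann cells, TGF-β pathway components, TGF-β target genes, cell cycle, apoptosis, oxidative phosphorylation, glycolysis, interferon response, NF-kB and chemokine genes, antioxidant response, sterol and fatty acid synthesis, immediate early genes, and autophagy and lysosome. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 27 lists. Member genes were also counted with p-values adjusted over the list alone. No list was chosen on these samples.

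Genes named in the text followed a rule fixed at the same time. It took Sel1l, the 12 largest rises and 12 largest falls among genes past the threshold whose group values did not overlap, up to 4 called members of each list or the 2 with the highest mean where none was called, and 23 genes of the β-cell, ER and TGF-β questions, of which 21 were measured. The other 2 were not analysed here. Gene models without a proper name were passed over for the next gene. A further 52 genes were added after their values had been seen, among them the members called over a list alone, relatives of named genes and other genes past the threshold. Xist, the Y-linked genes and the genes called only with the sex covariate were also named after their values had been seen.

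The gene and list tests were tested on simulated data built from the means and spreads of the 22180 genes, with 20 simulations. limma recovered 12.7% of genes changed by 0.5 on the log2 scale, 68.3% of those changed by 1 and 95.1% of those changed by 2, and 4.25% of its calls were false. A list shifted by 0.3 was found in 100% of the simulations, and 0.385% of unshifted lists were called, with genes drawn independently of each other. On the real arrays some lists were correlated, with estimates of 0.69 for ATF4 and CHOP targets and 0.44 for endothelial markers, while others lay near 0. These list rates therefore do not carry over to the real lists. The gene rates rest on normal noise, with each gene's observed spread taken as its true spread. They may not carry over to the real arrays either. The number of arrays limits the precision, and an exact permutation test of 3 against 3 arrays cannot give a two-sided p under 0.1.

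Alternatives fixed before the data were examined were quantile normalization again, arrays shifted to a common median, a filter for the brighter genes, the replicate number as a block, array weights, the mean over probe sets, a variance prior with trend and robust, the ordinary equal-variance test, all probe sets of the table, an estimated inter-gene correlation, the rotation test fry, which tests a list against no change, camera on ranks, and leaving out each array in turn. A covariate for sex-linked transcripts, the 4 arrays with female-type transcripts alone, and TGF-β target genes without matrix and contractile genes were added after the data were seen.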

Results

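The series profiled pancreatic islets, the clusters of endocrine cells that hold the insulin-producing β cells, from mice aged 5 weeks. Sel1L is an adaptor of the HRD1 ubiquitin ligase complex, which removes misfolded proteins from the endoplasmic reticulum by ER-associated degradation (ERAD). The title of the series names the maintenance of β-cell identity and TGF-β signalling as its subjects, and the design compares wildtype with β-cell-specific Sel1L-deficient islets, with 3 arrays per genotype. Values are log2 RMA summaries as deposited, with array medians from 3.08 to 3.16. Pearson correlations across genes were 0.991 to 0.992 within wildtype, 0.989 to 0.992 within Sel1L-deficient and 0.988 to 0.991 between genotypes, genes not being independent replicates. The first principal component held 29.9% of the variance. It placed the wildtype arrays at -11.7, -6.05 and -23.0 and the Sel1L-deficient arrays at 18.7, 24.7 and -2.61.

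The labels give female for all 6 samples, but the arrays differed in sex-linked transcripts. Xist, the RNA that coats the inactive X chromosome, stood at 2.93 in wildtype replicate 3 and 3.08 in Sel1L-deficient replicate 3, against 9.93 to 10.4 on the other 4 arrays. The Y-linked genes Kdm5d, Eif2s3y and Uty stood at 5.39 to 7.31 on these 2 arrays and at 1.20 to 2.07 on the others. Each genotype held 1 such array.

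Sel1l itself was 1.87-fold lower in Sel1L-deficient islets. Its log2 value was 8.59 ± 0.15 (SD, n = 3) in wildtype and 7.69 ± 0.04 (SD, n = 3) in Sel1L-deficient islets, a difference of -0.90 ± 0.11 (SE; limma, Benjamini-Hochberg adjusted p = 0.0312). The wildtype arrays read 8.46, 8.56 and 8.76 and the Sel1L-deficient arrays 7.73, 7.65 and 7.68, so Sel1l on every array went with the genotype label. Islets also hold cells in which the gene was not deleted, and where the probes of this set lie relative to the deleted part was not analysed here.

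Several genes of mature β cells were lower in Sel1L-deficient islets, while most measured members of their list did not pass the threshold. Mafa, a transcription factor of mature β cells, fell 4.33-fold, from 8.68 ± 0.06 to 6.57 ± 0.13 (SD, n = 3 each; log2 difference -2.11 ± 0.11 SE, limma adjusted p = 0.000681). Ucn3, a peptide hormone of mature β cells, fell 3.99-fold (from 9.22 ± 0.31 to 7.22 ± 0.28, SD, n = 3 each; limma adjusted p = 0.013). Slc2a2, which encodes the glucose transporter GLUT2, fell 2.60-fold (log2 difference -1.38 ± 0.16, limma adjusted p = 0.0265). Nnat, neuronatin, fell 2.53-fold on its brighter probe set (adjusted p = 0.0496), while the difference on the other was -0.35.

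Of the 22 measured members of the mature β-cell identity list, 6 fell, 0 rose and 16 did not pass the threshold. The other 2 that fell were Pcsk1, a convertase that processes proinsulin, by 2.07-fold, and G6pc2, an islet glucose-6-phosphatase subunit, by 1.87-fold (limma adjusted p = 0.041 and 0.0449). Adjusted over the list alone, 11 members fell and 1 rose. Those that passed only over the list alone were Pdx1 with a log2 difference of -0.66, Nkx6-1 with -0.56, Trpm5 with -0.51, Ins2 with -0.50, Nkx2-2 with -0.43 and, on the higher side, Cox6a2 with 1.06. Cox6a2 overlapped between genotypes, with 6.90 in wildtype replicate 3 and 6.81 in Sel1L-deficient replicate 3 (limma adjusted p = 0.385 over all genes). Over all genes the adjusted p was 0.196 for the transcription factor Pdx1, 0.263 for Nkx6-1 and 0.279 for the insulin gene Ins2, each lower on all 3 Sel1L-deficient arrays than on any wildtype array. Iapp, Glp1r and Slc30a8, also genes of β cells, differed by -0.09, -0.06 and -0.07. Iapp and Slc30a8 were likewise lower on all 3 Sel1L-deficient arrays than on any wildtype array, while Glp1r overlapped. Their group means lay at 11.1 to 11.7, where differences can be compressed. The list was shifted down with a median of -0.30 (camera, adjusted p = 4.33e-11), and adjusted p = 0.257 with an estimated correlation.

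**Figure D1:**
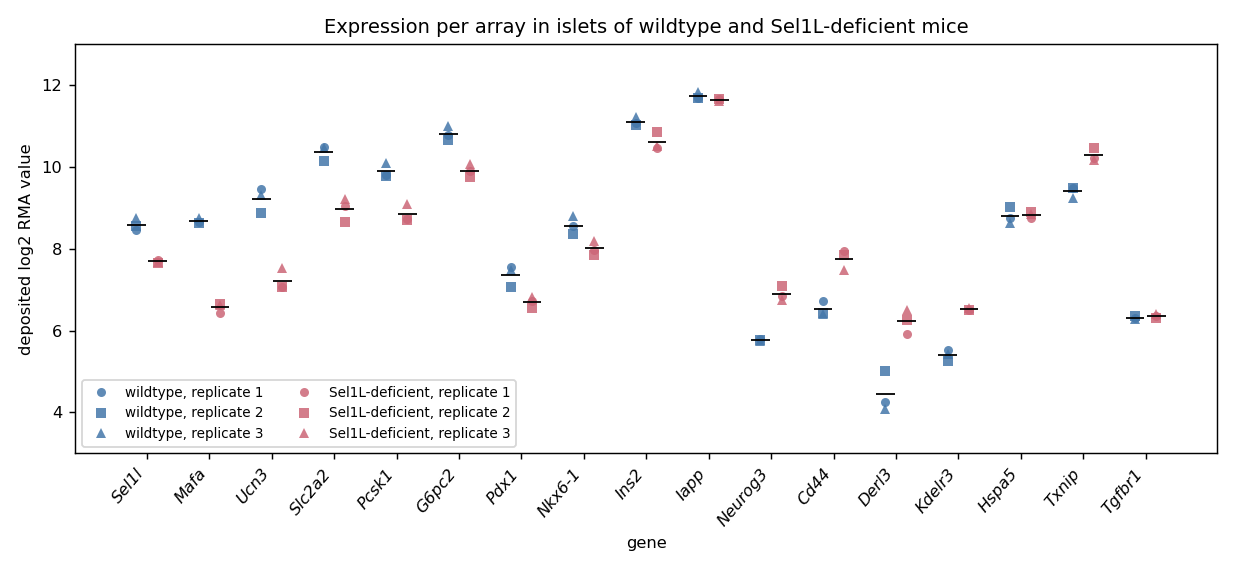
Deposited log2 RMA values of 17 genes (x axis) on each array, with wildtype arrays in blue, Sel1L-deficient arrays in red, a marker shape per replicate number and black bars for group means. Mafa lies near 8.68 in wildtype and near 6.57 in Sel1L-deficient islets, while Iapp, Hspa5 and Tgfbr1 overlap or nearly overlap between genotypes.

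Across all 22180 genes, 20 rose and 34 fell in Sel1L-deficient islets, 54 in total, and 13 of the rises and 15 of the falls were at least 2-fold. The named genes that rose most were Gbp11, a guanylate-binding protein, by 6.76-fold (log2 difference 2.76 ± 0.23, limma adjusted p = 0.00746) and Plppr5 by 3.98-fold. Derl3, an ERAD component, rose 3.42-fold. Tenm4, a teneurin adhesion protein, rose 3.07-fold on its brighter probe set, with a difference of 0.65 on the other. Trim66 rose 2.70-fold, Bmp3 2.41-fold, and Cd44, a hyaluronan receptor, 2.37-fold. Ntng1, Neurog3, Kdelr3, Snhg18 and Dnah9 rose 2.03-fold to 2.19-fold. The smallest adjusted p among these 12 was 0.00413, for Tenm4, and the largest 0.0435, for Bmp3. An odorant receptor model, Olfr330, also rose, from 1.86 to 4.43. The wildtype means of Olfr330, Ntng1 (2.06) and Gbp11 (2.91) lay below the array medians and were not separated from background, so the folds of Ntng1 and Gbp11 are not exact. That of Trim66, 3.18, lay just above the highest array median of 3.16, so its fold is not exact either.

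Besides Mafa, Ucn3, Slc2a2 and Nnat, the largest falls were in Tmem215 by 4.71-fold (log2 difference -2.24 ± 0.19, limma adjusted p = 0.00746) and in Ppp1r1a, an inhibitor subunit of protein phosphatase 1, by 3.50-fold. Plk3, a polo-like kinase, fell 3.31-fold and Ttyh1 fell from 4.26 to 2.58, the latter below the array medians. Sytl4, which encodes the granule-docking protein granuphilin, fell 3.16-fold. Hpgds fell 2.51-fold, Cbs, the enzyme cystathionine β-synthase, 2.20-fold, and Hpse, heparanase, 2.16-fold on its brighter probe set, with 0.04 on the other. In all 54 genes the 3 values of one genotype lay above the 3 of the other, as they did in 15.1% of all genes, where chance gives 10%. For the 54 this follows largely from their selection on the same arrays and adds no support. Leaving out 1 array gave 10, 9 and 7 genes without wildtype replicates 1, 2 and 3, and 4, 7 and 29 without Sel1L-deficient replicates 1, 2 and 3. Mafa, Plk3, Tmem215 and Tenm4 passed in all 6 of these fits. The covariate for the sex-linked transcripts marks replicate 3 of each genotype, so it cannot be told apart from anything else those arrays share. With it 63 genes passed, 46 of them shared. The 8 that did not had limma adjusted p from 0.0507 to 0.0651, Derl3 (0.0507) and Cd34 (0.0517) among them. 1 gene passed on the 4 arrays with female-type transcripts alone.

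**Figure D2:**
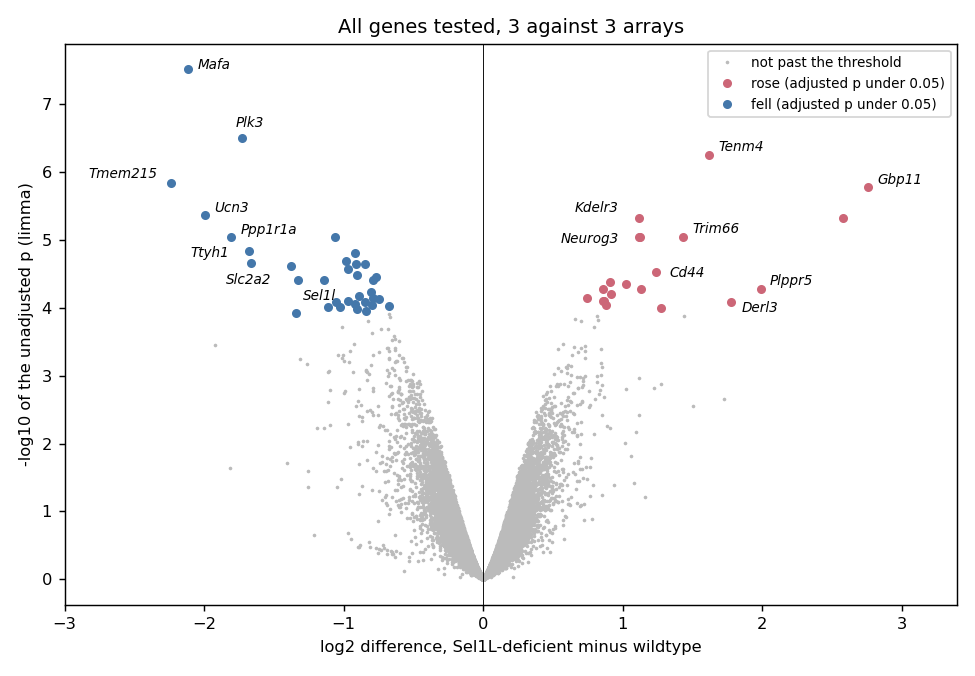
Log2 difference, Sel1L-deficient minus wildtype (x axis), against -log10 of the unadjusted limma p (y axis) for 22180 genes. Red points mark the 20 genes that rose and blue points the 34 that fell past the adjusted threshold, with Mafa the highest point.

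The fixed gene lists were tested as groups with camera, which found 5 shifted up and 5 shifted down of 27. With an estimated correlation 0 of the 10 passed, with adjusted p = 0.313 for oxidative phosphorylation and adjusted p = 0.257 for the other 9 lists. At an unadjusted p under 0.05 camera had 4 lists with the estimated correlation and 16 with the preset one. Correlation among members was not the only reason, since the TGF-β target list had an estimate of -0.000817, below the preset 0.01. limma's fry, which tests a list against no change and not against all other genes, called 0, with 11 lists at an unadjusted p under 0.05. Of the 10 ways to split the 6 arrays into 3 and 3, those other than by genotype gave 1 to 8 shifted lists.

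The ERAD machinery, the pathway Sel1L belongs to, had 1 member that rose and 1 that fell among 19 measured, with 17 that did not pass, and the counts were the same when adjusted over the list alone. Derl3, a derlin of the ER membrane, rose and Sel1l fell. The ubiquitin ligase gene Syvn1, which encodes the partner HRD1, differed by 0.02 with a 95% interval of -0.21 to 0.26, and the lectin gene Os9 by 0.02 with an interval of -0.20 to 0.24. The list median was 0.02 while camera's direction was down (adjusted p = 0.95).

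Genes of ER chaperones and the unfolded protein response did not shift as a group. Of 24 members 0 rose and 1 fell, and adjusted over the list alone 1 rose and 1 fell. Ero1b, the ER oxidase of β cells, fell 1.89-fold (log2 difference -0.92 ± 0.13, limma adjusted p = 0.0428). Creld2 passed only over the list alone, with a difference of 0.42. The chaperone BiP gene Hspa5 differed by 0.02 with a 95% interval of -0.26 to 0.31 and Xbp1 by -0.11 with -0.33 to 0.11. The list median was 0.01 (camera, adjusted p = 0.707), and it lay between -0.04 without wildtype replicate 3 and 0.07 without wildtype replicate 2. Kdelr3, a receptor that returns proteins to the ER and not a list member, rose 2.17-fold (limma adjusted p = 0.013).

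ATF4 and CHOP targets had 0 of 22 members past the threshold, over all genes and adjusted over the list alone, with a median of -0.07 (camera, adjusted p = 0.074). Ddit3, which encodes CHOP, differed by 0.30 (adjusted p = 0.667), Slc3a2 by -0.12 and Asns by -0.31. Ddit3 differed by 0.15 without wildtype replicate 2 and by 0.49 without wildtype replicate 3, and without the latter Asns differed by -0.12 and Slc3a2 by -0.03. Without wildtype replicate 1 the list passed at 0.00162, without wildtype replicate 2 at 0.00476 and without Sel1L-deficient replicate 2 at 0.0327, while without wildtype replicate 3, where the list was highest, the median was 0.08 (adjusted p = 0.292). The medians of the 3 fits that passed were -0.20, -0.12 and -0.12. Those of the others were -0.04 without Sel1L-deficient replicate 1, -0.05 without Sel1L-deficient replicate 3, -0.12 among the brighter genes and 0.09 on the 4 arrays with female-type transcripts. Apoptosis genes had 1 of 14 that rose, also when adjusted over the list alone. It was Txnip, a thioredoxin-binding protein induced by glucose, which rose 1.84-fold (limma adjusted p = 0.043; list median 0.08, camera adjusted p = 0.12). The apoptosis median was 0.18 without wildtype replicate 2, 0.03 without wildtype replicate 3, 0.05 on the 4 arrays with female-type transcripts and -0.09 among the brighter genes.

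TGF-β pathway components were higher as a group in Sel1L-deficient islets, with a median of 0.20 over 23 members (camera, adjusted p = 0.00132, and adjusted p = 0.257 with an estimated correlation). No single member passed over all genes (0 rose and 0 fell; at an unadjusted p under 0.05 the count over all 22180 genes was 2103), and adjusted over the list alone 1 rose. It was Tgfbr3, the co-receptor betaglycan, with a difference of 0.60 (limma adjusted p = 0.145 over all genes). The activin receptor Acvr2b differed by 0.49 and Smad4 by 0.24, or by 0.14 without wildtype replicate 2. The type I receptor Tgfbr1 differed by 0.04 with a 95% interval of -0.18 to 0.26, and Tgfb1 by 0.15 with -0.17 to 0.47. Leaving out an array gave 0.05 to 0.26 for Tgfb1, without wildtype replicates 3 and 2.

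TGF-β target genes had a median of 0.11 over 24 members (camera, adjusted p = 0.0204, and adjusted p = 0.257 with an estimated correlation), with 0 members past the threshold over all genes and 0 adjusted over the list alone. Cdkn1a, a cell cycle inhibitor, differed by 0.39, Skil, a feedback inhibitor of the pathway, by 0.35, and Smad7 by 0.26 (limma adjusted p = 0.461, 0.454 and 0.574). Without wildtype replicate 1 Smad7 differed by 0.15. The median was 0.18 without Sel1L-deficient replicate 2. The list did not pass without wildtype replicate 3 (0.0982), on the 4 arrays with female-type transcripts (0.0695, median 0.06), or without its matrix and contractile genes, where the median was 0.05 (adjusted p = 0.116). Those genes are also made by mesenchymal cells.

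Markers of endothelial and mesenchymal cells were higher in Sel1L-deficient islets. The endothelial list had a median of 0.38 over 14 members (camera, adjusted p = 1.05e-06, and adjusted p = 0.257 with an estimated correlation). None of its members passed over all genes (0 rose), and 6 rose adjusted over the list alone: Tie1 with 0.58, the VEGF receptor gene Kdr with 0.55, Eng with 0.51, Pecam1 with 0.44, Robo4 with 0.41 and Emcn with 0.36. The mesenchymal list had a median of 0.35 over 15 members (camera, adjusted p = 4.21e-05, and adjusted p = 0.257 with an estimated correlation), with 0 past the threshold over all genes and 1 adjusted over the list alone, Lum, at 0.47. Its means of 2.31 and 2.78 lay below the array medians and were not separated from background, so that difference is not exact. The median was 0.13 without wildtype replicate 3 and 0.21 without Sel1L-deficient replicate 1, with the list still past the threshold (0.00827 and 0.00225). Rgs5 of pericytes differed by 0.72 (limma adjusted p = 0.461) and Sparc by 0.45. Rgs5 overlapped between genotypes, with 6.88 in wildtype replicate 3 and 6.85 and 6.73 in Sel1L-deficient replicates 1 and 2. Cd34, a surface protein of vessels and progenitor cells outside the lists, rose 1.68-fold (limma adjusted p = 0.041, and 0.0517 with the covariate for sex-linked transcripts).

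Neurog3, the transcription factor that starts the endocrine program in the embryo, rose 2.18-fold, from 5.76 ± 0.03 to 6.89 ± 0.18 (SD, n = 3 each; limma adjusted p = 0.0156). It was the 1 of 16 members of the progenitor and dedifferentiation list that passed over all genes. Adjusted over the list alone 3 rose, the others being Serpina7 with 1.02 and Cd81 with 0.41. Aldh1a3, a dehydrogenase of dedifferentiated β cells, differed by 0.36 with a 95% interval of -0.08 to 0.80, by 0.15 without Sel1L-deficient replicate 1 and by 0.56 without Sel1L-deficient replicate 3. The list median was 0.12 (camera, adjusted p = 0.00145, and adjusted p = 0.257 with an estimated correlation), 0.24 without wildtype replicate 1, 0.19 without wildtype replicate 2 and 0.24 among the brighter genes. Of the 28 β-cell disallowed genes, normally silent in β cells, 0 passed over all genes and 0 adjusted over the list alone. Ldha, at 2.98 and 3.13 no higher than the array medians, differed by 0.14 and Zfp36l1 by 0.35, with 0.23 on its other probe set (list median 0.06, camera adjusted p = 0.074). That list passed without wildtype replicate 1 (0.0428) and without Sel1L-deficient replicate 3 (0.0462), with a median of 0.11 in the latter fit. The median was 0.10 without wildtype replicate 2 (0.119), 0.03 without wildtype replicate 3 (0.161), 0.02 without Sel1L-deficient replicate 2 (0.256) and 0.10 among the brighter genes (0.0511).

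None of the hormone genes of the other islet cells that were named passed the threshold. The glucagon gene Gcg differed by 0.03 with a 95% interval of -0.19 to 0.26, the somatostatin gene Sst by -0.03 with -0.25 to 0.20, and Ppy by 0.15 with -0.10 to 0.41. The peptide YY gene Pyy differed by 0.25 with an interval of -0.00378 to 0.496 (limma adjusted p = 0.535) and was higher on all 3 Sel1L-deficient arrays than on any wildtype array. The group means of all 4 lay at 12.1 to 12.6, near the highest values of the arrays, where differences can be compressed. Among 8 α-cell markers 0 passed over all genes and 2 rose adjusted over the list alone, Irx1 with 0.56 and Slc38a5 with 0.37 (list median 0.10, camera adjusted p = 0.119). That list passed among the brighter genes (0.0416, median 0.17). Markers of δ, PP and ε cells had 0 of 9 past either threshold, over all genes or adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.248). It was 0.07 without wildtype replicate 2, 0.07 without Sel1L-deficient replicate 1, 0.04 without Sel1L-deficient replicate 3 and 0.08 on the 4 arrays with female-type transcripts. Insulin granule and exocytosis genes had 1 of 21 that fell, Sytl4, also adjusted over the list alone, with a median of -0.06 (camera adjusted p = 0.0681). That list passed without wildtype replicate 1 (0.0201) and without Sel1L-deficient replicate 2 (0.0436), while the median was -0.02 without Sel1L-deficient replicate 3 (0.201) and 0.00 on the 4 arrays with female-type transcripts (0.464).

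**Figure D3:**
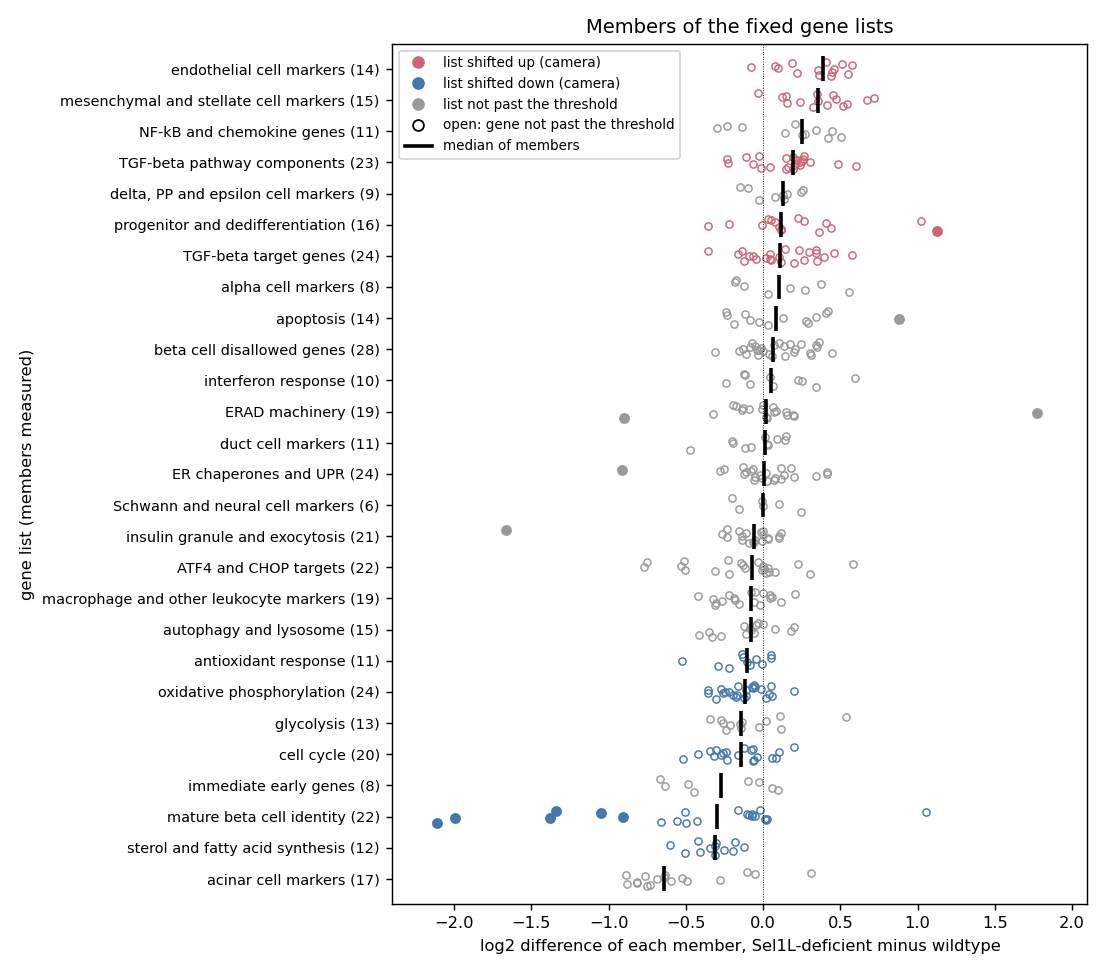
Log2 difference of each measured member, Sel1L-deficient minus wildtype (x axis), for the 27 gene lists ordered by median (y axis, number measured in brackets). Filled points passed the gene threshold, black bars are medians, and red or blue marks lists that camera found shifted up or down. The mature β-cell identity list reaches from -2.11 to 1.06.

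Genes of lipid synthesis and of oxidative phosphorylation were lower as groups. All 12 measured members of sterol and fatty acid synthesis lay below 0, with a median of -0.31 (camera, adjusted p = 5.99e-07, and adjusted p = 0.257 with an estimated correlation). Over all genes 0 fell, and adjusted over the list alone 4 fell: the squalene epoxidase gene Sqle with -0.50, Elovl6 with -0.42, the regulator Srebf1 with -0.34 and the fatty acid synthase gene Fasn with -0.31. Oxidative phosphorylation genes had a median of -0.12 over 24 members (camera, adjusted p = 0.00227, and adjusted p = 0.313 with an estimated correlation), with 0 past the threshold over all genes and 0 adjusted over the list alone. Sdhb and Cycs both differed by -0.36, with -0.50 to -0.20 over the 5 probe sets of Cycs, and the ATP synthase gene Atp5b by -0.16. Glycolysis genes had 0 of 13 past the threshold over all genes and 1 that rose adjusted over the list alone, Pdk1 with 0.54, whose other probe set gave -0.02. The glycolysis median was -0.14 (camera adjusted p = 0.133), -0.08 without wildtype replicate 1 (0.234) and -0.08 without Sel1L-deficient replicate 1 (0.312), and Gapdh and Pkm differed by -0.26 and -0.35.

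Cell cycle genes had a median of -0.14 over 20 members (camera, adjusted p = 0.00316, and adjusted p = 0.257 with an estimated correlation), and of -0.24 among the brighter genes. Over all genes 0 fell, and adjusted over the list alone 1 fell, the cyclin gene Ccna2 with -0.52. Ccnd2, the D-type cyclin of β cells, differed by -0.31 and Mki67 by -0.07 with a 95% interval of -0.68 to 0.55. Antioxidant response genes had a median of -0.10 over 11 members (camera, adjusted p = 0.0349, and adjusted p = 0.257 with an estimated correlation). Over all genes 0 fell, and adjusted over the list alone 1 fell, Srxn1 with -0.53. That list did not pass without wildtype replicate 3 (0.121), without Sel1L-deficient replicate 1 (0.0598) or 3 (0.115), or on the 4 arrays with female-type transcripts (0.222).

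Acinar cell markers varied widely between arrays of the same genotype. The median difference over 17 members was -0.64 (camera, adjusted p = 0.064). The mean of the list relative to its average read 0.157, -0.506 and 1.17 on the wildtype arrays and -1.01, -0.971 and 1.15 on the Sel1L-deficient arrays. Replicate 3 of each genotype was thus the highest. The list passed without Sel1L-deficient replicate 3 (1.02e-08, median -1.57), without wildtype replicate 2 (0.0038, median -1.19) or 1 (0.0428), and with the covariate for sex-linked transcripts (9.92e-07). Without wildtype replicate 3 the median was -0.12 (0.821), without Sel1L-deficient replicate 1 it was -0.21 (0.737) and without Sel1L-deficient replicate 2 it was -0.19 (0.494). The protease gene Ctrb1 differed by -0.49 and Cpa1 by -0.75, from -0.14 to -0.92 and from -0.12 to -1.60 when an array was left out, and 0 members passed over all genes or adjusted over the list alone.

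In the remaining lists 0 members passed over all genes and 0 adjusted over the list alone. Duct markers had a median of 0.01 over 11 members, with a mean of -0.06 and a downward camera direction (adjusted p = 0.704); Krt7 differed by -0.12 and Tspan8 by 0.15. Leukocyte markers had a median of -0.08 over 19 members (camera adjusted p = 0.134), with the class II gene H2-Ab1 at -0.27 (-0.51 to -0.09 when an array was left out) and Cd68 at -0.02. Schwann and neural markers had a median of 0.00 over 6 members (camera adjusted p = 0.988), with Ngfr at 0.11 and Fabp7 at -0.20. Interferon response genes had a median of 0.05 over 10 members (camera adjusted p = 0.795), with Usp18 at 0.04 and Ddx58 at -0.12. NF-kB and chemokine genes had a median of 0.25 over 11 members (camera adjusted p = 0.059), with Nfkbia at 0.27 and Birc3 at -0.14. Immediate early genes had a median of -0.27 over 8 members (camera adjusted p = 0.116), with Egr1 at -0.64 (-1.13 to -0.16 when an array was left out) and Jun at 0.06. Autophagy and lysosome genes had a median of -0.08 over 15 members (camera adjusted p = 0.074), with the cathepsin gene Ctsb at -0.41 and Lamp1 at -0.33. Leukocyte markers passed without wildtype replicate 3 (0.0231) or Sel1L-deficient replicate 2 (0.0277), with a median of -0.14 in the latter fit. Their median was -0.02 without wildtype replicate 1 (0.9), -0.15 without wildtype replicate 2 (0.122), -0.04 without Sel1L-deficient replicate 1 (0.671) and -0.20 among the brighter genes (0.145). Immediate early genes passed without wildtype replicate 1 (0.0176) or Sel1L-deficient replicate 2 (0.000319, median -0.51). Their median was -0.01 without Sel1L-deficient replicate 3 (0.57), -0.12 without wildtype replicate 2 (0.96), -0.17 without Sel1L-deficient replicate 1 (0.403), -0.45 among the brighter genes (0.165) and -0.12 on the 4 arrays with female-type transcripts (0.426). Autophagy genes passed without wildtype replicate 1 (0.0428) or Sel1L-deficient replicate 2 (0.0459), and had a median of -0.02 without wildtype replicate 3 (0.254) and of -0.01 on the 4 arrays with female-type transcripts (0.365). NF-kB genes passed without wildtype replicate 1 (0.0428) or Sel1L-deficient replicate 1 (0.0267) or 3 (0.0142). Without Sel1L-deficient replicate 2 their median was 0.03 (0.509), among the brighter genes it was 0.14 (0.6), and the mean of the list relative to its average was 0.364 on that array against -0.0375 and -0.0639 on the other Sel1L-deficient arrays. Interferon genes turned downward without Sel1L-deficient replicate 2 (0.0459, median -0.09). Their median was -0.01 without wildtype replicate 2, 0.22 without Sel1L-deficient replicate 1, 0.14 without Sel1L-deficient replicate 3, 0.13 among the brighter genes and 0.20 on the 4 arrays with female-type transcripts. Leaving out an array gave medians of -0.12 to 0.05 for duct markers and of -0.07 to 0.09 for Schwann markers.

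The wildtype mice carried no Cre recombinase, so this comparison does not separate the loss of Sel1l from the presence of the Cre allele. Islets spent a night in culture before RNA extraction, and the values describe whole islets and not sorted β cells.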

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

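The covariate for sex-linked transcripts, the fit on the 4 arrays with female-type transcripts and the shortened TGF-β target list were chosen after the data were seen. The number of genes past the threshold was 54. It was 58 after quantile normalization again, 52 with a common median, 64 among the brighter genes, 54 with array weights, 52 with the mean over probe sets and 63 with the covariate. It moved to 133 with a trend and robust variance prior, 53 of them shared. It was 0 with the ordinary equal-variance test, which found 1916 genes at an unadjusted p under 0.05 against 2103 with limma. It was 3 over all rows of the table, 2 of them shared, and 1 on the 4 arrays with female-type transcripts. The cause of these moves was not tested. Leaving out each array gave 4 to 29 genes and 9 to 17 lists. Of these genes 4 passed in all 6 such fits and 27 in at least 1. Ctsb and Cd81 passed only with the trend and robust prior.

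With the replicate number as a block 36 genes passed, 28 of them shared, and Sel1l had an adjusted p of 0.0559. The residual correlations of same-numbered arrays were 0.105, 0.072 and 0.210, against -0.133 to 0.041 for the other pairs between genotypes. Each array thus correlated best with its own number, a hint from the data and not from the design. Replicate 3 of each genotype also shared Y-linked transcripts and the highest acinar markers, which can raise its value without pairing. Group means were removed within each genotype, so these correlations are not independent of each other. Whether the numbers pair the samples stays open. With the block 13 lists were shifted, the added ones being acinar markers (8.65e-08), immediate early genes (0.00586) and NF-kB genes (0.0358).

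The number of shifted lists was 10. It moved to 0 with a correlation estimated per list and to 0 with fry, which has another null hypothesis. The cause was not tested. Correlation among members cannot alone account for the former. The TGF-β target list had an estimated correlation of -0.000817, below the preset 0.01, yet its unadjusted camera p went from 0.00679 to 0.0399. The number of shifted lists was 9 after quantile normalization again, which lost the antioxidant list. It was 11 with ranks, with array weights and with the covariate, each adding acinar markers. It was 10 with a common median, with the mean over probe sets and among the brighter genes, which lost the antioxidant list and added α-cell markers (0.0416). On the 4 arrays with female-type transcripts it was 11, with 8 shared and acinar (4.04e-10), leukocyte (0.0351) and NF-kB (0.0351) lists added. The mature β-cell, progenitor, endothelial, mesenchymal, TGF-β component, cell cycle, oxidative phosphorylation and sterol lists passed in all 6 fits that left out an array. The planned repeat of the mature β-cell list without the gene at the Cre insertion site was not run because that gene was not analysed here.

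Directions turned for results that lay near 0 and had not passed, and the cause was not tested. After quantile normalization again Cd68 was 0.0061, Gclm 0.0214 and the ERAD list, whose test turned upward, had a median of 0.0451. The ERAD test also turned upward among the brighter genes (0.0215), on ranks (0.0215), with the mean over probe sets (0.0239) and on the 4 arrays with female-type transcripts (0.0213). The test of the Schwann list turned upward while its median stayed below 0, with a common median (-0.0164), the replicate block (-0.0031) and fry (-0.0031). On the 4 arrays Slc3a2 was 0.0023, Cat 0.0890, Cd68 0.119, Ddx58 0.103, Gclm 0.0564, Hspa5 -0.0671, the ATF4 list 0.0901 and the Schwann list 0.139. Leaving out arrays gave ranges of -0.142 to 0.123 for Cat, -0.107 to 0.0909 for Cd68, -0.233 to 0.0846 for Ddx58, -0.0223 to 0.311 for Gbp7, -0.0646 to 0.0687 for Gclm, -0.0586 to 0.131 for Hspa5 and -0.0408 to 0.131 for Id2. The ranges were -0.0982 to 0.228 for Jun, -0.0891 to 0.281 for Ldha, -0.329 to 0.207 for Mki67, -0.0334 to 0.378 for Ngfr, -0.0022 to 0.0477 for Os9, -0.0784 to 0.0097 for Sod1, -0.0494 to 0.0112 for Sst, -0.0233 to 0.0703 for Syvn1 and -0.0779 to 0.147 for Usp18. Without a change of sign they were -0.0929 to -0.0188 for Glp1r, -0.113 to -0.0432 for Iapp, 0.0034 to 0.0716 for Gcg, 0.0751 to 0.199 for Ppy, 0.0230 to 0.0636 for Tgfbr1, -0.181 to -0.0321 for Krt7, 0.0585 to 0.211 for Tspan8, -0.478 to -0.0085 for Fabp7 and -0.208 to -0.106 for Atp5b. List medians ranged from -0.198 to 0.0834 for ATF4 targets, -0.0017 to 0.0249 for ERAD, -0.0393 to 0.0703 for ER chaperones, -0.0701 to 0.0942 for Schwann, -0.117 to 0.0549 for duct and -0.0872 to 0.218 for interferon genes.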

Other observations

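All tests of explanations here were chosen after the results were seen, except the counts over other splits of the arrays. Some genes outside the named rule that passed the threshold follow, picked after their values were seen and not as a group. Fh1, the fumarase of the citric acid cycle, fell 1.73-fold, Oxct1, an enzyme of ketone body use, 1.74-fold, and Maob, a monoamine oxidase, 1.86-fold (limma, Benjamini-Hochberg adjusted p = 0.041, 0.043 and 0.041). The serine and one-carbon genes Psat1, Shmt2, Phgdh and Mthfd2 differed by -0.77, -0.75, -0.53 and -0.51 with none past the threshold (limma adjusted p from 0.287 to 0.552). They were picked from the ATF4 list, and without wildtype replicate 3, which was high in them, the differences were -0.40, -0.51, -0.25 and -0.31. The vesicle gene Syt5 fell 1.73-fold, and the neurotrophin receptor gene Ntrk2 fell 2.09-fold (limma adjusted p = 0.032 and 0.0156). Plut, a long noncoding RNA beside Pdx1, fell 1.60-fold (limma adjusted p = 0.0435), and Ifi30, a lysosomal thiol reductase, 1.71-fold.

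Relatives of genes that rose differed less in value, and no difference between relatives was tested. Kdelr1 and Kdelr2 differed by 0.15 and 0.17, where Kdelr3 rose by 1.12 on the log2 scale. Tenm2 and Tenm3 differed by 0.19 and 0.11 beside Tenm4, and Gbp7 and Gbp9 by 0.09 and 0.70 beside Gbp11. Gbp9, with a wildtype mean of 2.91 below the array medians, differed by 0.33 without Sel1L-deficient replicate 2 and by 0.44 without wildtype replicate 3. Without Sel1L-deficient replicate 2 Tenm2 differed by 0.11, without wildtype replicate 3 Tenm3 by 0.05 and without wildtype replicate 1 Kdelr1 by 0.09. Quantile normalization again and a common median kept each of these directions. With the covariate for sex-linked transcripts, 8 of the 54 genes did not pass, Derl3 (limma adjusted p = 0.0507), Cd34 (0.0517), Pax7 (0.0519) and Plut (0.0651) among them. 17 further genes did, 5 that rose and 12 that fell. Among these 17 the polymeric immunoglobulin receptor gene Pigr differed by 1.44, Dcdc2a by 1.50, Car10 by -1.26 and Lyve1, a receptor of lymphatic vessels and macrophages, by -1.10 (limma adjusted p from 0.0084 to 0.0454). A single probe set that names several genes also passed over all 41345 probe sets, with a difference of -1.82 (limma adjusted p = 0.0464).

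The 6 arrays can be split into 3 and 3 in 10 ways. The split by genotype gave 54 genes, and the highest of the others gave 1. It gave 10 shifted lists, and the highest of the others gave 8. In each case 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

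The mature β-cell list was lower, with 6 of 22 members past the threshold and adjusted p = 0.257 with an estimated correlation, which a lower share of β cells in the islets might produce. Such a loss would lower genes made only in β cells by a common log2 amount. Of 10 list members picked for this test after the results were seen, 7 departed from their common shift beyond a 95% interval. Large falls and flat genes were pooled in that choice, and whether each of the 10 is made only in β cells was not tested. A gene also made in other islet cells would fall less, so the count alone does not decide the question. Mafa and Nkx6-1, named before the data were examined, read 8.68 and 8.57 in wildtype. They differed by -2.11 (95% interval -2.36 to -1.87) and -0.56 (-0.89 to -0.23), which are unlike falls. A lower share alone would not give these if both genes are made only in β cells, which was not tested here. Mafa and Ucn3 deviated from the common shift by -1.28 and -1.16 on the log2 scale, and Glp1r, Slc30a8 and Iapp by 0.78, 0.76 and 0.74. The latter 3 read above 11, where the scale can compress differences, so part of the spread may be technical. A lower share as part of the cause stays open, as do regulation within β cells and an effect of the Cre allele.

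Endothelial and mesenchymal markers were higher, and the TGF-β lists shifted up with them, with 0 members past the threshold over all genes and all 4 lists at adjusted p = 0.257 with an estimated correlation. A lower share of β cells would raise every other resident cell type alike; the endothelial minus leukocyte shift was 0.441, with a 95% interval of -0.178 to 1.06, which leaves that explanation open. The endothelial shift was also above the duct shift, by 0.386 (95% interval 0.0943 to 0.678), but ducts are carried over during isolation and can vary on their own. The intervals of the differences to α cells, δ, PP and ε cells, mesenchymal, Schwann and acinar cells included 0. The mean shift was 0.116 (95% interval 0.0308 to 0.201) for α-cell markers. It was 0.0811 (-0.00956 to 0.172) for δ, PP and ε markers. How large a rise a lower share of β cells would give was not measured. Without its matrix and contractile genes the TGF-β target list had a median of 0.05 (adjusted p = 0.116), and whether its genes were higher in β cells or in mesenchymal cells stays open.

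Replicate 3 of each genotype carried Y-linked transcripts although the labels give female. Per gene, the smallest gap between these 2 arrays and the other 4 was 3.38 on the log2 scale for Kdm5d, with 4.60 for Eif2s3y and 5.31 for Uty, values that fit RNA from male animals. A pool that held a fair share of female islets would keep Xist high, but it lay 6.84 lower on the log2 scale, which argues against such a pool. Sel1l stood at 8.76 in wildtype replicate 3 and 7.68 in Sel1L-deficient replicate 3, near the 8.46 and 8.56 and the 7.73 and 7.65 of the other arrays, which argues against an exchange between genotypes. All 6 labels give female, so no exchange among these samples brings Y-linked transcripts, and whether the sex labels are wrong or samples from outside the series came in stays open.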
